A study of Rattus norvegicus with 64 samples.

How the data were processed

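RNA was sequenced from liver and kidney of 32 Sprague Dawley rats, 8 for each combination of agent (acetaminophen or vehicle) and collection time (5 h or 10 h), which gave 64 libraries. Groups were taken from the agent, tissue and time labels. Per the labels' protocols, RNA was extracted with TRIzol and made into stranded libraries of poly-A messenger RNA; the extraction text speaks of cultured cells, while the tissue labels name liver and kidney. Library numbers come from the sample titles. The labels name no sex, batch or animal, and liver and kidney libraries of the same rat cannot be matched, so no pairing was used.

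The authors deposited 1 kallisto table per library with estimated counts and TPM per transcript (kallisto 0.42.4 and genome build Rnor 6.0, per the submitters' processing notes). Per the file headers, the estimated counts are kallisto's counts of reads assigned to each transcript, not normalized, and the deposited TPM are scaled to transcript length and library size. The same 28420 transcripts and lengths stand in all 64 files, and 26.6% of the estimated counts are not whole numbers (tolerance 1e-06). The effective length differs from the length by the same number of bases for 96.6% of the transcripts. Reads that fit several transcripts, of one gene or of near-identical genes, are divided by kallisto's model, and no measure of that uncertainty was used here. A change of a single transcript can therefore come from reads moving between related transcripts.

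The transcript identifiers could not be paired with gene symbols: 0 of the 28420 occur in the reference table. The tests were run per transcript, as the plan laid down for that case. The 44 planned gene lists could not be run, and the planned naming rule, which took several genes with symbols per comparison, could not be applied. It was reduced, after the data were seen, to 1 transcript that rose and 1 that fell per tissue. These are, in the acetaminophen comparison with more calls, the largest rise and the largest fall among called transcripts with a mean log2 CPM of at least 1 and all 8 acetaminophen libraries on the same side of the vehicle mean.

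Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM scaling, glmQLFit and glmQLFTest, two-sided). The 32 libraries of a tissue were fitted together with 4 groups, and all 64 with 8 groups for differences between tissues. A transcript is called at a Benjamini-Hochberg adjusted p under 0.05 over all transcripts tested. After the filter, 14943 transcripts were tested in liver, 17284 in kidney and 18016 over both. The median standard error of a log2 change was 0.19 in liver and 0.13 in kidney for a comparison of 2 groups. Standard errors are the log2 change divided by the square root of the F statistic. The estimated counts per library ranged from 21467448 to 29496773 in liver and from 18039111 to 26148119 in kidney. CPM in the text are estimated counts scaled to the library's total. No 2 libraries of a group agreed within sampling noise: the smallest chi-square per degree of freedom was 14.0.

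Alternatives fixed before the data were examined were DESeq2 size factors, no filter, DESeq2 1.42.0, limma 3.58.1 on log2(TPM + 1) and log2(TPM + 0.1), limma voom with sample quality weights, robust edgeR, a fit of only the groups compared, a fit without the 4 libraries numbered 65 to 68, and the library total as a covariate. The libraries 65 to 68 follow the run of 1 to 64 in number, and they are liver 5 h acetaminophen replicate 8, liver 5 h vehicle replicates 7 and 8, and kidney 5 h acetaminophen replicate 8. After the data were seen, fits without liver libraries 28, 29, 30 and 32, without kidney libraries 44 and 56, with the library's slope on transcript length or its number as a covariate, and without each library in turn were added, as were the transcript groups, the overlap ratios and the response score. The slope on transcript length is the regression of a library's deviation in log2 CPM (prior count 2) on log2 length.

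Liver-enriched and kidney-enriched transcripts have a mean of at least 1 TPM and at least 16 times the TPM of the other tissue (0.01 added) in vehicle libraries of the other time, and shared transcripts have at least 1 TPM in both and differ by at most 2 times. These groups and the 200 most abundant transcripts were tested with limma's camera, with a preset correlation of 0.01 and adjustment over the 4 groups of a comparison. Overlaps are set against the product of the list sizes divided by the transcripts tested in both. Scores were compared by exact permutation tests, two-sided.

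The tests were tried on simulated negative binomial counts with the means, dispersions and library sizes of these libraries and 200 changed transcripts. For the liver 5 h comparison with 14943 transcripts, edgeR recovered 37.3% of the 1.5-fold, 68.7% of the 2-fold and 78.8% of the 4-fold changes. For the kidney 10 h comparison with 17284 transcripts it recovered 47.8%, 82.1% and 92.4%, and for the difference between kidney times with 17284 transcripts 38.8%, 56.7% and 87.9%. For the difference between tissues at 5 h with 18016 transcripts it recovered 22.4%, 41.8% and 74.2%. Unchanged transcripts were called as well: 10 of 133 calls in the liver 5 h simulation, 2 of 125 for liver 10 h, 13 of 111 for the difference between liver times and 7 of 129 for vehicle livers. In kidney they were 5 of 147 at 5 h, 9 of 157 at 10 h, 7 of 129 for the difference between times and 9 of 148 for vehicle kidneys, and between tissues 10 of 102 at 5 h and 8 of 103 at 10 h. In all but liver 10 h and kidney 5 h this share was above the 0.05 that the threshold allows on average, in 1 simulation each.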

Results

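The series measured how messenger RNA levels in the liver and kidney of Sprague Dawley rats changed after a high dose of acetaminophen, an analgesic that injures the liver in overdose. A total of 32 rats received either 2 g/kg acetaminophen or the vehicle, polyethylene glycol at 50% in a volume of 6 ml/kg, and liver and kidney were taken 5 h or 10 h later. This gave 64 libraries in 8 groups of 8, and each group held 8 separate rats. The estimated counts per library ranged from 21467448 to 29496773 in liver and from 18039111 to 26148119 in kidney. The 10 most abundant transcripts held 21.6% to 28.3% of the counts of a liver library and 17.5% to 24.6% of those of a kidney library. Each of the 64 libraries correlated better with the other libraries of its own tissue than with those of the other tissue. The features are transcripts with Ensembl identifiers, which neither the files nor the reference table used here pair with gene symbols, so the changes are described by groups of transcripts and 4 identifiers.

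The first comparison asked which liver transcripts differed between acetaminophen and vehicle at 5 h. Of 14943 transcripts tested, 1102 rose and 977 fell, which is 13.9% of those tested. The transcripts that rose did so by a median log2 change of 0.56, and those that fell by a median of -0.62. A log2 change of 1 or more was seen in 213 of those that rose and 200 of those that fell. Transcripts that rose held 6.33% ± 0.954 of the counts in the vehicle libraries and 10.3% ± 0.638 in the acetaminophen libraries, and those that fell held 5.69% ± 0.411 and 3.50% ± 0.381 (SD, n = 8 each). ENSRNOT00000001875 lay between 26.4 and 297 CPM (estimated counts scaled to the library's total) in the 8 vehicle libraries and at 612 ± 397 CPM (SD, n = 8) with acetaminophen, a log2 change of 2.32 ± 0.44 (SE; edgeR adjusted p = 4.96e-04). The 297 CPM belong to vehicle replicate 6, and the acetaminophen libraries began at 274. Fitted on the 16 libraries of this time alone, the test called 1277 transcripts. Which direction held more calls was not stable: without vehicle replicate 6, 888 rose and 1162 fell, and the share that rose was 43.7% with DESeq2 size factors, 44% by DESeq2 and 42.5% without a filter. On the authors' TPM, which carry no correction for composition, 12.1% of the 2976 transcripts called had risen, against 53% here, and all fold changes shifted by a median of -0.18.

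At 10 h the liver held 1455 transcripts that rose and 909 that fell, together 15.8% of the 14943 tested. With DESeq2 size factors 1216 rose and 1030 fell. Of the fits without 1 library, that without acetaminophen replicate 8 had the smallest excess of rises, 1096 against 919. On TPM 63.7% of the calls had risen, against 61.5% here. Changes of 1 or more on the log2 scale were found in 192 that rose and 251 that fell. Those that rose held 8.02% ± 0.523 of the counts in vehicle libraries and 13% ± 1.22 in acetaminophen libraries, and those that fell held 10.8% ± 0.347 and 7.05% ± 0.66 (SD, n = 8 each). ENSRNOT00000019192 rose the most of the transcripts that met the naming rule: it went from 16.5 ± 4.55 to 403 ± 140 CPM (SD, n = 8 each), a log2 change of 4.62 ± 0.38 (SE; edgeR adjusted p = 1.45e-09). The same transcript had 28.9 ± 13.3 CPM in vehicle and 35.3 ± 29.8 in acetaminophen livers at 5 h (SD, n = 8 each; edgeR adjusted p = 0.513). ENSRNOT00000055333 fell by 2.69 ± 0.77 on the log2 scale (SE; edgeR adjusted p = 0.0147), from 4.77 ± 2.31 to 0.748 ± 0.67 CPM (SD, n = 8 each). It was scarce, at least 1 acetaminophen liver had no count for it, and on log2(TPM + 1) the change was -1.09, with the call kept.

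**Figure D1:**
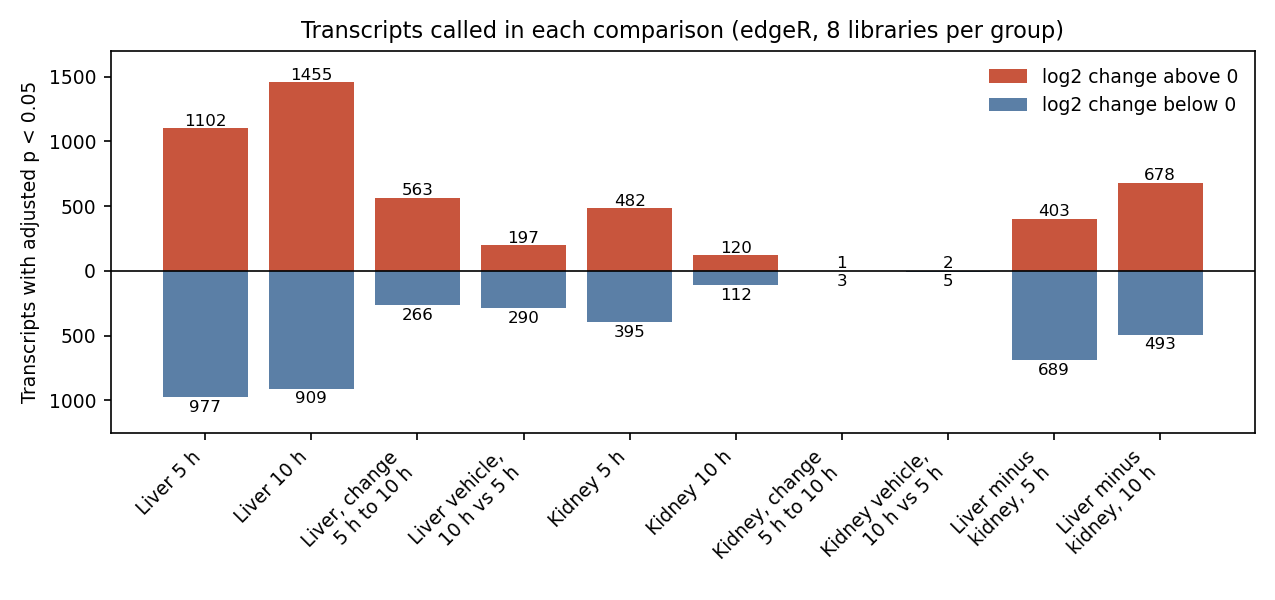
Number of transcripts with an edgeR adjusted p under 0.05 in each of the 10 comparisons (vertical axis, transcripts); bars above 0 count positive and bars below 0 negative log2 changes. Liver had 2079 calls at 5 h and 2364 at 10 h, and kidney had 877 and 232.

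The liver lists at the 2 times overlapped in part. Among transcripts that rose, 333 were called at both times, where independent lists would share 107. Among those that fell, 279 were called at both, where independent lists would share 59.4. Another 47 fell at 5 h and rose at 10 h, and 11 rose at 5 h and fell at 10 h, where independent lists would share 95.1 and 67. These comparisons share no libraries. The test of the difference between the times called 829 transcripts, 563 with a more positive and 266 with a more negative effect at 10 h. Of these, 294 rose at 10 h without a call at 5 h, 162 fell at 5 h without a call at 10 h, 117 rose at 5 h without a call at 10 h, and 105 fell at 10 h without a call at 5 h. ENSRNOT00000019192 was among them, with an effect larger by 4.25 ± 0.48 on the log2 scale at 10 h (SE; edgeR adjusted p = 1.89e-06). ENSRNOT00000055333 differed by -4.34 ± 1.06 (SE, edgeR adjusted p = 0.0131). That includes a rise of 1.65 ± 0.735 at 5 h that was not called (SE, edgeR adjusted p = 0.137). It went from 1.33 ± 1.11 CPM in vehicle to 3.84 ± 3.67 in acetaminophen livers at 5 h (SD, n = 8 each). At least 1 of those vehicle livers had no count for it. ENSRNOT00000001875 differed by -1.99 ± 0.60 (SE, edgeR adjusted p = 0.0443). The last call is fragile: it was lost without a filter (adjusted p = 0.0646), with the library total as a covariate (adjusted p = 0.106), with the library number as a covariate (adjusted p = 0.05) and without the libraries numbered 65 to 68 (adjusted p = 0.152). It was also lost without 5 h vehicle replicate 1, 2, 3, 5, 7 or 8, 5 h acetaminophen replicate 1, 3 or 8, 10 h vehicle replicate 1, 2, 6, 7 or 8, or 10 h acetaminophen replicate 2, 3, 4, 5, 6, 7 or 8 (each left out singly, edgeR adjusted p from 0.0527 to 0.0806, log2 difference from -2.04 to -1.76). On TPM the same difference gave 1849 calls, 93.7% of them positive, against 67.9% here, with all values shifted by a median of 0.18. The limma voom test with library weights gave 1258.

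Vehicle livers were compared between 10 h and 5 h to show what differed between the collection times without acetaminophen. A total of 487 transcripts differed, of which 197 were higher and 290 lower at 10 h. The count was 1671 by limma voom with library weights, 914 on TPM with 15.6% of the calls higher at 10 h, 809 by DESeq2, 735 on these 16 libraries alone and 292 with the library total as a covariate. It fell to 321 or 314 without 5 h vehicle replicate 1 or 2, and to 323 or 307 without 10 h vehicle replicate 4 or 5.

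In kidney at 5 h, 482 of 17284 transcripts rose and 395 fell, or 5.07% of those tested. The median log2 change was 0.47 for those that rose and -0.50 for those that fell, and 91 and 34 of them changed by 1 or more. Transcripts that rose went from 2.48% ± 0.113 to 3.61% ± 0.642 of the counts, and those that fell from 1.87% ± 0.0403 to 1.36% ± 0.161 (SD, n = 8 each). ENSRNOT00000001875 rose here as in liver, from 11.5 ± 6.31 to 77.7 ± 58.4 CPM (SD, n = 8 each), a log2 change of 2.75 ± 0.46 (SE; edgeR adjusted p = 5.12e-04). ENSRNOT00000041084 had a log2 change of -3.0 ± 0.82 (SE; edgeR adjusted p = 0.0294), from 6.65 ± 4.10 to 0.788 ± 1.46 CPM (SD, n = 8 each), but vehicle replicate 8 had no count for it either. At 10 h its log2 change was 0.64 (edgeR adjusted p = 0.804), and the difference between the times did not pass the test (edgeR adjusted p = 0.27). The call at 5 h was lost by limma voom (adjusted p = 0.27), on the 16 libraries of this time alone (edgeR adjusted p = 0.155) and without acetaminophen replicate 2 or 5 or vehicle replicate 5 or 6 (edgeR adjusted p = 0.0661, 0.0602, 0.0508 and 0.0504). The test on the 16 libraries alone called 247 transcripts, and the count was 420, 511 or 541 without acetaminophen replicate 2, 4 or 5. On TPM, 35.3% of the calls had risen, against 55% here.

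At 10 h in kidney, 120 transcripts rose and 112 fell, or 1.34% of those tested, with median log2 changes of 0.58 and -0.60. Those that rose held 0.783% ± 0.0533 of the counts in vehicle and 1.14% ± 0.109 in acetaminophen libraries, and those that fell held 1.38% ± 0.113 and 0.920% ± 0.0681 (SD, n = 8 each). The count varied widely with the method: 1065 by limma voom with library weights, 426 by DESeq2, 379 on the 16 libraries of this time alone and 508 without the kidney libraries numbered 44 and 56. It was 140, 141, 154, 136 or 131 without acetaminophen replicate 1, 3, 4, 7 or 8, 353 without acetaminophen replicate 6, and 113 or 148 without vehicle replicate 6 or 8. On TPM 26.5% of the calls had risen, against 51.7% here.

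The kidney lists overlapped by 41 transcripts that rose at both times, where independent lists would share 3.35, and by 20 that fell at both, where they would share 2.56. None rose at one time and fell at the other, where independent lists would share 3.12 and 2.74. The test of the difference between the kidney effects at 5 h and 10 h called 4 transcripts by edgeR, while 1228 had an unadjusted p under 0.05 and chance alone gives 864. Of the 4, 2 rose and 1 fell at 5 h without a call at 10 h, and 1 fell at 10 h without a call at 5 h. DESeq2 called 68, limma voom 64 and limma on TPM 1. The edgeR count moved by more than 1.5 times for 25 of the 32 libraries when each was left out. It was 0 without 5 h vehicle replicate 2, 3, 4 or 7, 5 h acetaminophen replicate 2, 4, 5 or 7, 10 h vehicle replicate 4, 6 or 8, or 10 h acetaminophen replicate 1, 3, 4, 5, 7 or 8. It was 10, 21 or 46 without 5 h acetaminophen replicate 1, 3 or 6, 1 or 8 without 5 h vehicle replicate 5 or 8, 2 without 10 h vehicle replicate 2, and 10 or 24 without 10 h acetaminophen replicate 2 or 6. Between vehicle kidneys, 7 transcripts differed between 10 h and 5 h (2 higher and 5 lower), against 39 by DESeq2, 64 by limma voom, 12 on those 16 libraries alone and 14 without the libraries numbered 44 and 56. This count was 13 or 17 without 5 h vehicle replicate 5 or 8.

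**Figure D2:**
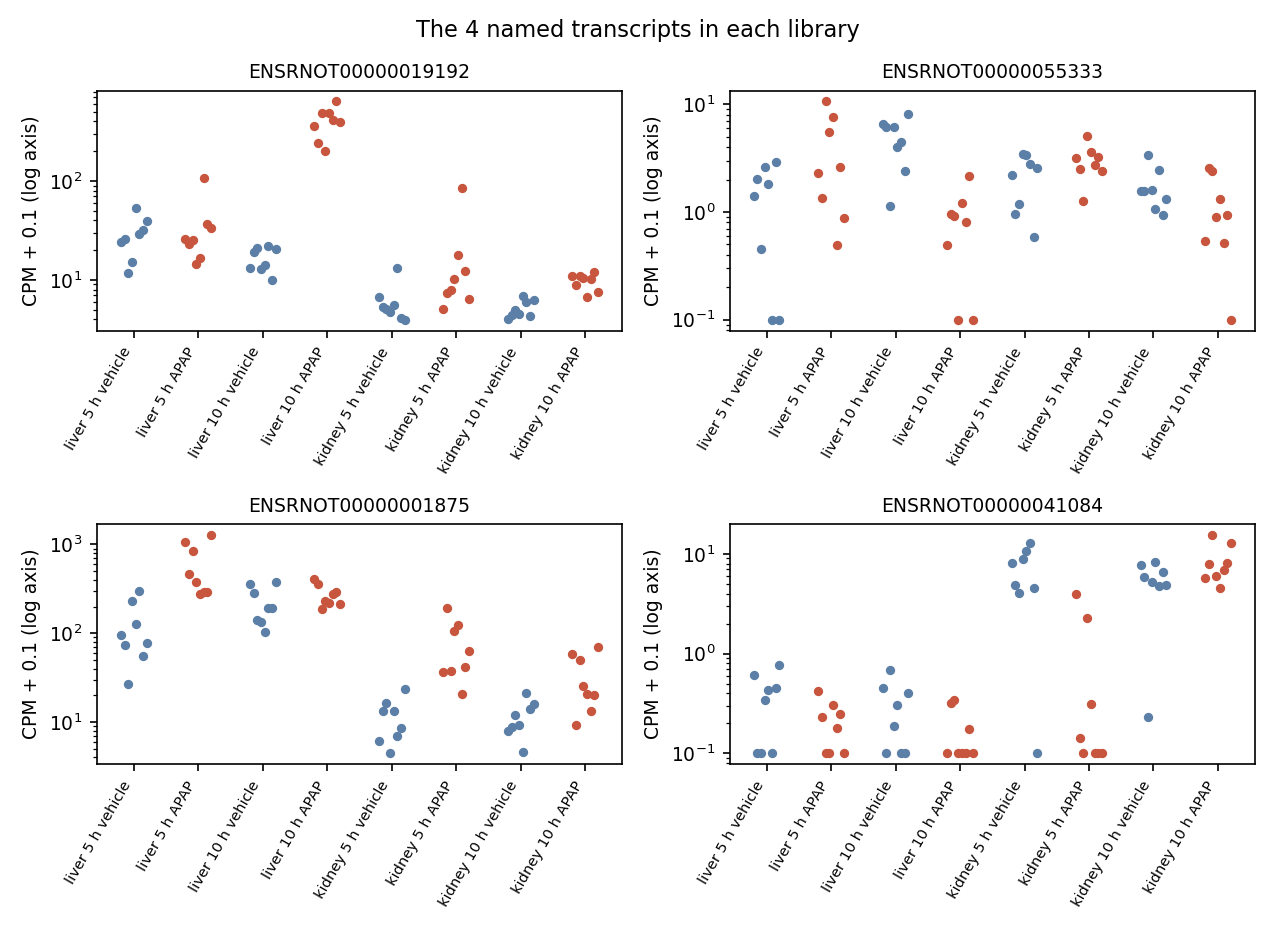
CPM plus 0.1 (vertical log axis) of the 4 named transcripts in all 64 libraries, by tissue, time and agent; each point is 1 library, blue for vehicle and red for acetaminophen (APAP). ENSRNOT00000019192 had 403 ± 140 CPM in acetaminophen livers at 10 h and 16.5 ± 4.55 in their vehicle controls (SD, n = 8 each).

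Whether liver and kidney responded differently was tested in a fit of all 64 libraries. That fit treats the libraries, which come from 32 rats, as independent and uses 1 estimate of the spread per transcript for both tissues. At 5 h the acetaminophen effect differed between the tissues for 1092 of 18016 transcripts, with 403 more positive and 689 more negative in liver. At 10 h it differed for 1171, with 678 more positive and 493 more negative in liver. Of the transcripts tested, 14432 passed the filter in each tissue alone, so the others were scarce in at least 1 tissue. Called differences reached 10.5 and -9.78 at 5 h and 13.5 and -13 at 10 h on the log2 scale. Called changes between acetaminophen and vehicle within a tissue reached at most 7.95 and -7.78. Called differences between the liver times, which also compare 2 effects, reached 8.77 and -11.4. How many of the calls come from transcripts scarce in 1 tissue was not counted. ENSRNOT00000019192 had a liver effect larger than the kidney effect by 3.67 ± 0.56 on the log2 scale at 10 h (SE; edgeR adjusted p = 6.11e-06). At 5 h its difference was -1.34 ± 0.54 (SE; edgeR adjusted p = 0.132), and in kidney at 5 h its log2 change was 1.67 ± 0.41 (SE; edgeR adjusted p = 0.0162), with acetaminophen replicate 6 at 84 CPM. Without that library the kidney change was 0.69 and the call was lost (edgeR adjusted p = 0.0735), as it was by limma voom (adjusted p = 0.11), on TPM (adjusted p = 0.0973) and on the 16 libraries of this time alone (adjusted p = 0.13). For ENSRNOT00000001875 the difference at 5 h was -0.49 ± 0.62 (SE; edgeR adjusted p = 0.735). Calls were also shared between the tissues: 115 transcripts rose and 69 fell in both at 5 h, where independent lists would share 32.0 and 21.5, and 28 rose and 21 fell in both at 10 h, where they would share 10.2 and 5.03. Both tissues came from the same rats, so the lists are not independent, and the labels do not say which libraries share a rat. At 5 h the count of differing transcripts was 609 on the 32 libraries of that time alone and 1670 on TPM. On TPM 17.4% of the calls at 5 h and 74.2% of those at 10 h were more positive in liver, against 36.9% and 57.9% here.

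Transcripts were then grouped by where vehicle animals express them, using the vehicle libraries of the other time so that the libraries compared took no part in the choice. In liver at 10 h, transcripts at least 16 times more abundant in liver than in kidney shifted down: 96 of 427 fell and 20 rose, while 6.08% of all tested transcripts fell. Their median log2 change was -0.17 (camera adjusted p = 9.75e-08, and adjusted p = 0.00351 with an estimated correlation). At 5 h, 38 of 423 liver-enriched transcripts fell and 26 rose, with a median of -0.08 (camera adjusted p = 0.0476, adjusted p = 0.335 with an estimated correlation, and adjusted p = 0.0903 without the libraries numbered 28, 29, 30 and 32). The 200 most abundant liver transcripts at 5 h included 19 that rose and 2 that fell (camera adjusted p = 0.031, and adjusted p = 0.531 with an estimated correlation). Of 3481 transcripts at similar levels in both tissues, 401 fell and 238 rose in liver at 5 h (camera adjusted p = 0.0476, and adjusted p = 0.272 with an estimated correlation). In liver, more kidney-enriched transcripts rose than fell, 53 against 14 of 813 at 5 h and 53 against 12 of 663 at 10 h. They held no excess of rises: 6.52% and 7.99% rose, against 7.37% and 9.74% of all tested transcripts. Fewer of them were called as falls, 1.72% and 1.81%, against 6.54% and 6.08%. Neither shift passed the test (camera adjusted p = 0.151 and 0.717). Without the libraries numbered 65 to 68, that at 5 h did (camera adjusted p = 0.0421). Kidney-enriched transcripts are scarce in liver, where 813 of 1886 and 663 of 1684 passed the filter. Shares of calls depend on the counts and were not compared at like abundance, so whether this group falls less often is not known. At 10 h, 515 of 4403 shared transcripts rose and 320 fell, as did 21 and 16 of the 200 most abundant, and neither group passed the test (camera adjusted p = 0.717 for both).

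In kidney at 5 h, 91 of 1839 kidney-enriched transcripts fell and 65 rose, with a median of -0.07 (camera adjusted p = 0.0322, adjusted p = 0.469 with an estimated correlation, and adjusted p = 0.188 without the libraries numbered 65 to 68). Of 223 liver-enriched transcripts measured in kidney, 10 rose and 0 fell at 5 h, with a median of 0.47 (camera adjusted p = 0.00284, and adjusted p = 0.897 with an estimated correlation). Liver-enriched transcripts held 0.903% of the counts of 5 h acetaminophen replicate 8 and 0.18% to 0.447% of those of the other 7 libraries of its group. Without the libraries numbered 65 to 68, which include it, the median was 0.11 (camera adjusted p = 0.935), and without those numbered 44 and 56 it was 0.40 (adjusted p = 0.112). With a ratio of 4 in place of 16, the adjusted p was 0.164 for both groups. Of 3480 shared transcripts 100 rose and 63 fell, and of the 200 most abundant 8 rose and 2 fell (camera adjusted p = 0.823 for both); the most abundant had a median of -0.01 and a mean of 0.03. At 10 h, 4 of 225 liver-enriched transcripts rose and 5 fell, 21 of 1643 kidney-enriched rose and 35 fell, 23 of 4405 shared rose and 15 fell, and 3 of the 200 most abundant rose and 3 fell. At 10 h in kidney no group of transcripts passed the test (camera adjusted p from 0.191 to 0.639), but the 200 most abundant transcripts did without the libraries numbered 44 and 56 (adjusted p = 0.0141).

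**Figure D3:**
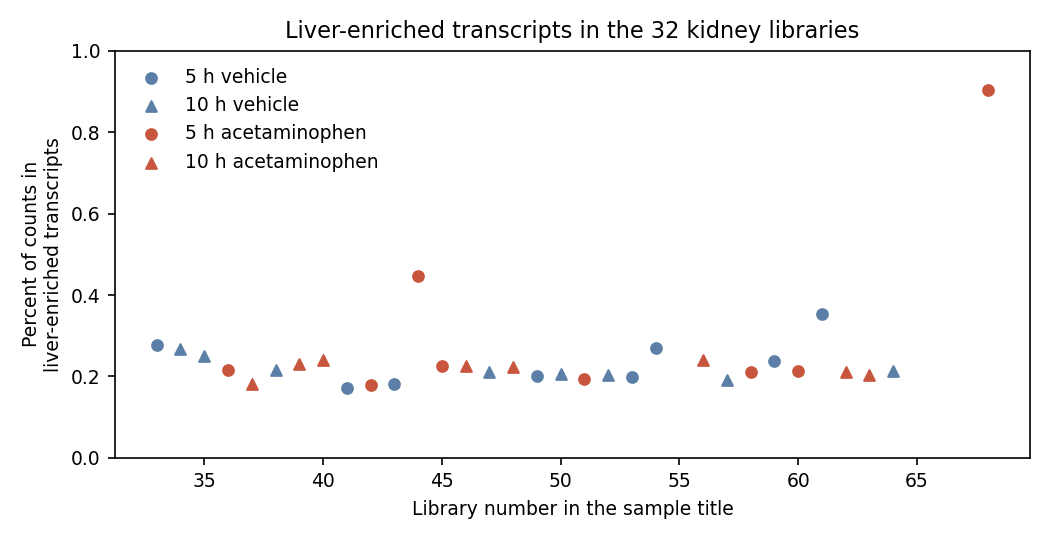
Percent of each kidney library's counts in liver-enriched transcripts (vertical axis) against the library number in the sample title (horizontal axis); circles are 5 h, triangles 10 h, blue vehicle and red acetaminophen. The library numbered 68 holds 0.903%, more than any other kidney library.

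A response score per library was the mean log2 CPM of the transcripts that rose minus that of the transcripts that fell at the other time, relative to the vehicle mean. In liver at 5 h it was 0.54 ± 0.14 in acetaminophen libraries around a vehicle SD of 0.23 (n = 8 each; exact permutation p = 6.22e-04, two-sided), and 5 of the 8 lay above the highest vehicle library. In liver at 10 h it was 0.58 ± 0.13 around a vehicle SD of 0.14 (n = 8 each), and all 8 lay above every vehicle library (exact permutation p = 1.55e-04, the smallest that 8 against 8 allows). In kidney the score was 0.59 ± 0.31 at 5 h around a vehicle SD of 0.28 (n = 8 each; exact permutation p = 0.0014), with 4 of the 8 above the highest vehicle library. These 4 lay at 0.794 to 0.995 and the other 4 at 0.227 to 0.348, so no library lay near the mean. At 10 h the kidney score was 0.42 ± 0.08 around a vehicle SD of 0.05 (n = 8 each, exact permutation p = 1.55e-04), with all 8 above. Adjusted over these 4 tests, the exact permutation p-values were 8.29e-04, 3.10e-04, 0.0014 and 3.10e-04.

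**Figure D4:**
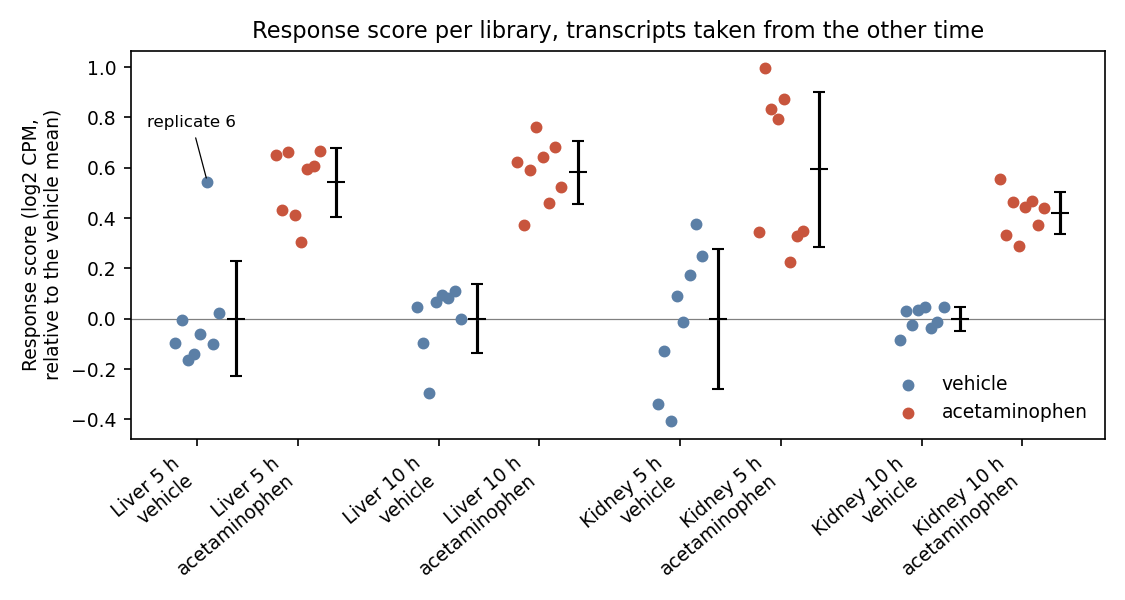
Response score of each library (vertical axis, log2 CPM relative to the vehicle mean) by tissue, time and agent; points are libraries and bars show the mean and SD of 8. All 8 acetaminophen libraries lie above every vehicle library at 10 h in both tissues, and liver 5 h vehicle replicate 6 lies at 0.54, within the range of the acetaminophen libraries.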

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

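The patterns weighed here were all noticed in these data, and 4 tests were chosen only after the result they measure was seen: the share of liver-enriched transcripts in the other kidney libraries, the scores of liver libraries 28, 29 and 32, the search for an exchanged label, and the kidney transcripts chosen at 10 h. In 56 tests of a group of 8 libraries for a library far from the others, 10 found one, and chance gives about 1 in 20, or 2.8.

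Liver 5 h vehicle replicate 6 had a response score of 0.543, while the other 7 vehicle libraries lay between -0.165 and 0.0217. Set against the mean of those 7, its score was 0.621, and the 8 acetaminophen libraries lay between 0.383 and 0.745, so none of them was at vehicle level as an exchange of labels would need. Removing each library's linear trend on transcript length left the score at 0.597, which argues against that bias. The liver libraries numbered 28, 29 and 32, which share the low slope on length of replicate 6, scored on average only 0.0304 above the rest of their groups. Their rises were -0.0664, 0.0734 and 0.0842 in that order. They are all acetaminophen libraries, and library 28 was scored on other transcripts. A quality problem common to the 4 therefore cannot be judged from them. Another score used 181 transcripts that rose and 266 that fell by 1 or more at 10 h, chosen without liver libraries 28, 29, 30 and 32. On these, vehicle replicate 6 scored 1.24, where the acetaminophen libraries had 0.786 to 1.71 and the other vehicle libraries -0.21 to 0.491. The library was singled out by its score on 10 h calls, so this is no independent evidence. A candidate explanation is an acetaminophen response in this library, whether by a single wrong label, a dosing error or a vehicle animal with a similar state. A fault of this library, alone or shared with the other libraries of low slope, is another. These cannot be separated with the labels at hand, and the library was kept in its labelled group.

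Kidney 5 h acetaminophen replicate 8, the library numbered 68, had 0.903% of its counts in liver-enriched transcripts, against 0.18% to 0.447% in the other 7 libraries of its group. Of the 50 most abundant of 433 liver-enriched transcripts, 223 of which passed the filter in kidney, 47 were higher in this library than in each of the other 7, but the library was singled out by the summed share of such transcripts, so the count is no independent evidence. The excess had a median of 1.76% of the liver level over the 50 (quartiles 1.36% and 1.97%). The other 7 acetaminophen libraries had a median of 0.214%, within the vehicle range of 0.171% to 0.354%, which argues against a response of the kidney to acetaminophen. Liver RNA in this library, by carry-over at dissection or at the bench, may be the source; the library is numbered directly after 3 liver libraries (65 to 67), and when in the work it arose was not tested.

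Kidney had 877 calls at 5 h and 232 at 10 h; without the libraries numbered 44 and 56 the counts were 1207 and 508, and the median SD within groups at 10 h was 0.877 of that at 5 h, which argues against these libraries and against a larger spread at 10 h as the whole cause. Transcripts chosen in 4 against 4 of the 5 h libraries changed by a mean of 0.48 in the other 5 h libraries and 0.24 at 10 h, lower in 20 of 20 splits, which is consistent with a smaller mean effect at 10 h. Transcripts chosen at 10 h in the same way changed by 0.44 in the other 10 h libraries and 0.33 at 5 h, lower in 17 of 20 splits, so part of the drop may be a change of which transcripts respond. The splits redraw the same libraries, so they are not independent of each other. The 5 h mean covers acetaminophen libraries that differ, with response scores of 0.794 to 0.995 in replicates 2 to 5 and 0.227 to 0.348 in the other 4, and the 5 h count was 420, 994, 511 or 541 without replicate 2, 3, 4 or 5. Fitted time by time the order turned, with 247 calls at 5 h and 379 at 10 h. That fit changes the scaling, the degrees of freedom and the estimate of the spread together. It shifted the log2 changes by a median of only -8.62e-05 at 5 h and 0.0037 at 10 h, which argues against the scaling. The degrees of freedom fall alike at both times, while the count fell at 5 h and rose at 10 h. The median SD within groups was 0.282 at 5 h and 0.248 at 10 h, and the shared fit gives both times 1 estimate of the spread. Whether that turned the order was not tested, so the drop from 877 to 232 calls may in part come from it.

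Other libraries far from their groups were liver 10 h acetaminophen replicate 8 (number 28) with a slope of -0.198 on transcript length, liver 5 h vehicle replicate 6 (number 30) with -0.132, and liver 10 h vehicle replicate 2 with 0.0432. Liver libraries 28, 29, 30 and 32, the last 4 of the liver numbers up to 32, had slopes of -0.198 to -0.0867, and the other 28 liver libraries -0.0414 to 0.0621. Tests of these slopes, also made after they were seen, gave 26 consecutive sets among the 23751 sets of 4 that the 29 liver libraries numbered up to 32 allow, totals above the median of the other 28 for all 4, and a median slope of 0.02 in the other acetaminophen livers, within the range of the other vehicle livers; this pattern is not weighed further. The 10 most abundant transcripts held 28.3% of the counts in liver 5 h vehicle replicate 6 (others 21.6% to 24.5%) and 25.9% in liver 10 h acetaminophen replicate 1 (others 21.8% to 23.6%). Kidney-enriched transcripts held 0.463% of the counts of liver 10 h acetaminophen replicate 5 (others 0.27% to 0.342%). On log2 CPM with a prior count of 2, ENSRNOT00000041084 was at -3.49 in kidney 5 h vehicle replicate 8 (others 2.07 to 3.61). That library had no count for it, so the value is set by the prior count. In kidney 10 h vehicle replicate 3 it was at -2.18 (others 2.23 to 3.05).

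By tests of the difference itself, the acetaminophen effect differed between 5 h and 10 h for 829 liver and 4 kidney transcripts, and between liver and kidney for 1092 transcripts at 5 h and 1171 at 10 h. ENSRNOT00000019192 differed by 4.25 and ENSRNOT00000055333 by -4.34 between the liver times, ENSRNOT00000001875 by -1.99 (a call lost without most single libraries), and ENSRNOT00000019192 by 3.67 between the tissues at 10 h, all on the log2 scale.

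Labels were also exchanged at random to see whether chance splits call as many transcripts. With agent labels exchanged within tissue and time, only the real split, 1 of 100, reached the 2079 calls of liver at 5 h (highest other 3) and the 2364 at 10 h (highest other 1). In kidney 1 of 60 splits reached 877 at 5 h (highest other 29) and 232 at 10 h (highest other 1). For the differences between tissues 1 of 40 splits reached 1092 at 5 h (highest other 132) and 1171 at 10 h (highest other 14). With time labels exchanged within agent, 1 of 80 splits reached the 829 liver transcripts whose effect changed (highest other 98) and the 487 of vehicle livers (highest other 1). In kidney 2 of 60 splits reached the 4 transcripts whose effect changed (highest other 8), and 1 of 60 the 7 of vehicle kidneys (highest other 0). For the other 9 counts the share was under 0.05, each taken alone, and only the real split reached the count. The labels of all groups in a fit were exchanged at once. Real agent or time effects therefore add to the spread in the other splits and can lower their counts. For the agent and vehicle comparisons the share alone therefore does not exclude chance. Between vehicle kidneys, 1002 transcripts had an unadjusted edgeR p under 0.05, where chance alone gives 864. For differences of effect between tissues or times, the share cannot decide whether chance explains the count, since the exchange removes those effects along with their difference. For the 4 kidney transcripts the share was also under 0.05, but 1 other split called more, and the count was 0 without a filter and 0 to 46 when each library was left out, so little rests on it.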

How the results depend on the processing

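The fits without liver libraries 28, 29, 30 and 32 or kidney libraries 44 and 56, with the length slope or library number as covariate, and without each library in turn were chosen after the data were seen, as were all alternatives for overlaps, transcript groups and scores. Of 130 alternative counts of transcripts, 99 stayed within 1.5 times of the reported count; the cause of the other changes was not tested unless stated. With only the groups compared in the fit the counts were 1277 in liver at 5 h, 735 between vehicle livers, 247 and 379 in kidney at 5 h and 10 h, 12 between vehicle kidneys and 609 between the tissues at 5 h. On log2(TPM + 1) they were 1849 for the change of the liver effect, 914 between vehicle livers, 1 for the change of the kidney effect and 1670 between tissues at 5 h; with 0.1 in place of 1 the first 3 were 1822, 815 and 1. Limma voom gave 1258 for the change in liver, 1671 between vehicle livers, 1065 in kidney at 10 h, 64 for the change in kidney and 64 between vehicle kidneys. DESeq2 gave 809 between vehicle livers, 426 in kidney at 10 h, 68 for the change in kidney and 39 between vehicle kidneys. The library total as covariate gave 292 between vehicle livers and 2 for the change in kidney, which no filter took to 0. The length slope as covariate gave 934 between vehicle livers and 1655 between tissues at 5 h. Without liver libraries 28, 29, 30 and 32 vehicle livers gave 803; without kidney libraries 44 and 56 kidney gave 508 at 10 h, 36 for the change and 14 between vehicles. Leaving out each library in turn gave 307 to 574 between vehicle livers, 420 to 1267 in kidney at 5 h, 113 to 353 at 10 h, 0 to 46 for the change in kidney and 5 to 17 between vehicle kidneys. No count in liver at either time moved by over 1.5 times in this way (1579 to 2191 at 5 h and 1990 to 2444 at 10 h), and in these refits none of the transcripts called there changed sign. Ratios of observed to chance overlap stayed above 1: for the liver times 3.1 (rose) and 4.69 (fell), moving to 5.32 and 7.35 with no filter, and for those that fell to 2.91 and 2.94 on the 2 TPM scales; for the kidney times 12.3 (rose), moving to 24.2 with no filter, 7.88 by DESeq2, 23 and 25.7 on TPM, 6.95 by voom, 22.6 fitted alone and 6.36 without libraries 44 and 56, and 7.81 (fell), moving to 13.4 with no filter; for liver and kidney at 5 h 3.59 (rose), moving to 6.34 with no filter and 6.81 and 7.11 on TPM. With DESeq2 size factors the log2 changes in liver at 5 h shifted by a median of -0.0348 over all transcripts, the largest such shift of the 10 comparisons, and the share of calls that rose went from 53% to 43.7%. All 24 alternatives for the response scores kept direction and call. For the 4 named transcripts in each comparison that called them, refits chosen after the data were seen where the comparison was not the one they were named in, 118 alternatives kept the call and 10 lost it, as 198 and 26 fits without a library did. The losses were all of ENSRNOT00000041084 in kidney at 5 h (adjusted p from 0.00375 to 0.27), ENSRNOT00000019192 in kidney at 5 h (0.00142 to 0.13) and the change of ENSRNOT00000001875 in liver (0.00367 to 0.152). Of 72 alternatives for transcript groups, 59 kept their side of the threshold, 11 lost the call and 2 gained it. In the simulation with 200 changed transcripts, 37.3% of the 1.5-fold changes were recovered for liver at 5 h. That simulation gave 133 calls and the data 2079, and the adjusted threshold is stricter with fewer calls. The share does not carry over to the data, so how many changes were missed there is not known. The planned tests of gene lists were not run, since the reference table used here paired no transcript with a symbol.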

Other observations

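In liver at 10 h, 22.5% of the liver-enriched transcripts tested fell and 4.68% rose, while 1.81% of the kidney-enriched ones fell and 7.99% rose. Of all transcripts tested there, 6.08% fell and 9.74% rose. The shift of the kidney-enriched group did not pass its test, and the difference between the groups was not tested. Kidney-enriched transcripts are scarce in liver, where 663 of 1684 passed the filter at 10 h, so the shares are not set at like abundance. At 5 h the shares for liver-enriched transcripts were 8.98% and 6.15%, for kidney-enriched ones 1.72% and 6.52%, and for all transcripts tested 6.54% and 7.37%.

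The tests of library number below were chosen after the scores had been seen. In vehicle kidneys at 5 h the response score rose with the library number in the sample title (Pearson r = 0.885, exact permutation p = 0.00414; Spearman rho = 0.881, exact permutation p = 0.00724; n = 8). Adjusted over the 8 groups in which the relation was computed, these became 0.0331 and 0.0579. Without the 2 libraries farthest from the median number, r was 0.897. In 6 other groups r was -0.127 to 0.435 (adjusted p from 0.751 to 0.771) and rho was -0.19 to 0.476 (adjusted p from 0.598 to 0.84), by exact permutation tests. Without the 2 farthest libraries, r in these 6 was -0.377 to 0.573 and changed sign in liver 10 h acetaminophen and kidney 10 h vehicle. In kidney at 5 h the scores of the acetaminophen libraries lay at 0.227 to 0.348 in 4 libraries and at 0.794 to 0.995 in the other 4, with no value between. The 4 high scores have the library numbers 42, 44, 45 and 51, and the 4 low ones 36, 58, 60 and 68, so the high scores lie in an unbroken run of this group's numbers. The relation over these 8 is the last of the 8 computed; no pooled value is given, since the scores form separate clusters, each too small for its own.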
